A study of Cunninghamia lanceolata with 2 samples.

How the data were processed

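Root RNA of Chinese fir (Cunninghamia lanceolata) seedlings was sequenced after 4 months at a phosphorus concentration below 0.01 mM (LP) or at 1 mM (CK, the phosphorus-sufficient control). Each group has 1 library. Per the labels' protocols, total root RNA was extracted with Trizol, poly(A) RNA was isolated on oligo(dT) beads and fragmented, and paired-end Illumina libraries were sequenced. The same protocol text also speaks of an adipose type and of both poly(A)- and poly(A)+ fractions, and the labels differ on the HiSeq model, so the RNA fraction is not certain; the tissue is taken from the sample labels. The assembler, aligner, counter and statistical test are not given in the sources used here. No genome was used, so genes are known by the identifiers and annotation text of the table alone.

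The table holds 32731 assembled genes of 201 to 12214 bases (median 610). The authors deposited estimated counts for each library, which are not normalized and need not be whole. They sum to 48502899 in LP and 17848911 in CK. The deposited RPKM values, per the file headers, give reads per kilobase of gene, scaled to the depth of the library. Dividing the estimated count by effective length and RPKM gave a library total within 10% of its median, close to the summed counts, for 85.9% and 91.3% of genes with at least 100 reads. The deposited log2 fold change equals log2 of LP RPKM over CK RPKM within 0.005 in 25479 genes with at least 1 RPKM in both libraries. The deposited p-value and FDR come from the authors' comparison of the 2 libraries and are rounded to 2 decimals. The deposited gene lengths and effective lengths, in bases, are common to both libraries, and the yes or no call for each gene is the authors' own. A product name is given for 8160 genes (24.9%) and any annotation text for 14777.

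The main value per gene was log2((LP + 1)/(CK + 1)) on RPKM, with a pseudocount of 1, for the 30843 genes with a mean RPKM of at least 1. This scale understates the fold of low genes. Genes at least 2-fold apart were counted. With 1 library per group no test was run and no p-value was computed, and a test on the reads of 2 libraries, such as that of the authors, compares those libraries and not the phosphorus levels. Folds of named genes are ratios of RPKM, or of reads per library total where a value lies under 1 RPKM. Their 95% intervals are exact (Clopper-Pearson) intervals of the read counts, rounded to whole reads, and cover counting error only. Where a library has 0 reads, the fold is a lower bound against a floor of 3 reads in that library, which at 1000 bases is 0.0619 RPKM in LP and 0.168 RPKM in CK.

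Before the data were examined, 27 gene lists were fixed as search patterns on the joined annotation columns, and the lists with at least 5 kept members are reported. Too small were cytosolic ribosomal proteins (0 members, because the pattern did not match the wording of the table) and WRKY, MYB, NAC and bHLH factors (1 member). A list's median log2 ratio is given with its order-statistic interval over members and with its percentile among 10000 random lists of the same size, matched in 20 bins of mean expression. These percentiles describe the 2 libraries and are not tests across plants. The random lists were drawn from the 14316 kept genes with annotation text, since only those can be list members. This pool was set after percentiles from all kept genes had been seen. With all kept genes as the pool, 9 lists lay above the 97.5th and 3 below the 2.5th percentile, against 10 and 2 with the annotated pool. The choice of the annotated pool is thus one made after the data were seen. The jasmonate and abscisic acid list (1.6 with all genes, 6.1 with annotated genes) and the photosynthesis list (97.3 and 99.1) changed sides. Log2 ratios were also taken relative to genes of the same abundance and length, in 10 bins of abundance and 10 of length within each. This adjustment was added after the data were seen, and the number of length bins was raised from 5 to 10 after the first result. Groups of genes that share a product name, and the scan of KEGG pathways, were likewise chosen after the data were seen.

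Named genes follow a rule set before the data were examined. It takes, among 4582 genes with a mean of at least 10 RPKM and a product name, the 10 highest and 10 lowest log2 ratios. It adds the 2 highest and 2 lowest members of each list with a mean of at least 2 RPKM, and the 10 most abundant genes of each library. Some of the 116 genes it takes are left unprinted. Product names and GO terms are those of the table and were not checked against sequence. Assembled genes can be fragments or near-identical copies that share reads, so values of single family members are uncertain.

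The calculation was tested on simulated data, with Poisson counts drawn from the mean levels and library sizes of the real genes (29284 genes kept). In these, 200 genes with a mean of at least 5 RPKM were changed, so recovery at lower levels was not tested. Of 50 genes changed 2-fold, 16 passed the 2-fold limit in the right direction, as did 48 of 50 at 3-fold, 50 of 50 at 4-fold and 50 of 50 at 8-fold. The counting interval held the true ratio for 96.9% of 2000 genes with 3 to 30 CK reads and for 95.1% of 2000 with more. Of 200 unshifted lists of 25 genes, 12 fell outside the middle range. Their genes were drawn at random, so this does not test lists of related genes. Alternatives covered the pseudocount, the filter, the scaling between libraries, the fold limit, the annotation searched, the weight of abundant genes and the authors' FDR limit. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.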

Results

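Gene expression was measured by RNA-seq in roots of Chinese fir seedlings kept for 4 months at low phosphorus (LP, below 0.01 mM) or with sufficient phosphorus (CK, 1 mM). The comparison asks which root transcripts differ between the phosphorus supplies. The LP library holds 48502899 estimated reads and the CK library 17848911, with a median of 143 and 54 reads per gene. The most abundant gene took 2.34% of the reads in LP and 1.35% in CK. Each group has 1 library, so no difference below has a replicate check, and "higher" and "lower" describe these 2 libraries. Intervals cover counting error only.

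Of the 25 gene lists, phosphate uptake and transport had the highest median and the highest ratio of summed values. Of its 22 genes, 18 were at least 2-fold higher in LP and 1 was at least 2-fold lower. Their median log2 ratio was 2.91 (95% interval over members 1.64 to 4.63), above all 10000 random lists. Their summed level was 1967 RPKM in LP against 209.7 RPKM in CK, 9.38 times as much. All 18 higher members belonged to the 19 annotated as inorganic phosphate transporters of the PHS family, a family of proton-coupled carriers. The 3 PiT family members stayed within 2-fold. The gene comp25863_c0, a PHS transporter, had 342 RPKM in LP and 0 reads in CK, at least 1320-fold higher. Its relative comp6435_c0 had 316 RPKM against 1.83 RPKM, 172-fold higher (101 to 324). The exception, comp19803_c0, had 1.28 RPKM in LP and 5.99 RPKM in CK, on 14 and 24 reads. In CK, 6 of the 22 genes had 0 reads.

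**Figure D1:**
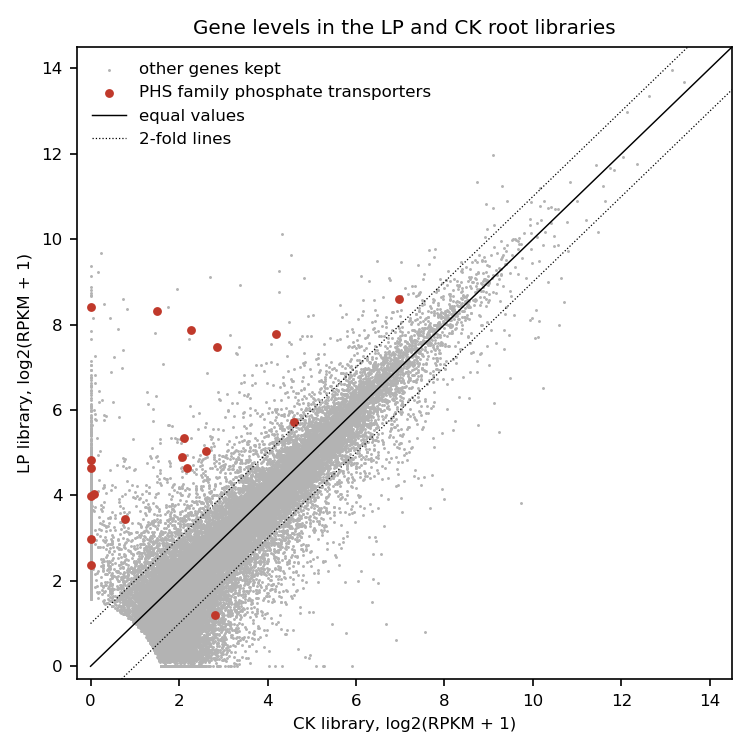
Level of each kept gene in the CK library (x axis) and the LP library (y axis), both as log2(RPKM + 1), with the 19 PHS family phosphate transporters in red, the line of equal values and the 2-fold lines. Of the red points, 18 lie above the upper 2-fold line and 1 lies below the lower line.

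Of 45 phosphatase and scavenging genes, which release phosphate from organic compounds, 16 were at least 2-fold higher, 1 was lower and 28 stayed within 2-fold, with a median log2 ratio of 0.43 (0.08 to 1.03), above all 10000 random lists. By product name, 4 of 7 acid phosphatases and 3 of 4 genes for ribonuclease T2, which degrades RNA, were at least 2-fold higher. The summed level of the 4 ribonuclease T2 genes was 11.42 times as high in LP, a larger ratio than that of the phosphate uptake list. The ribonuclease T2 gene comp17262_c0 had 84.7 RPKM in LP and 1.41 RPKM in CK (60.1-fold, 38.4 to 99.9). The gene comp26000_c0, with no product name but an acid phosphatase GO term, had 222 RPKM against 1.75 RPKM (127-fold, 89.9 to 186). The lowest member, comp18970_c0, carries inositol phosphate kinase terms beside the acid phosphatase term and was 16.1-fold lower (13.8 to 18.9). Of the list, 5 members are ribosomal protein L10e genes that carry an acid phosphatase term, and without them the median was 0.50.

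The 20 genes annotated to phosphate signalling did not share a direction. Of these, 8 were at least 2-fold higher and 4 lower, and the median of -0.15 lay at the 27.3rd percentile of random lists. Their summed level was 4.49 times as high in LP. Of the 8 higher members, 3 are PHS transporters that the uptake list also holds, comp6435_c0 among them. The 17 others had 5 higher and 4 lower, with a median of -0.29 at the 6.8th percentile (56.3rd after allowance for gene length). The gene comp25733_c0, whose GO terms name the cellular response to phosphate starvation, had 330 RPKM in LP and 0.76 RPKM in CK (428-fold, 274 to 710). Lower members were comp16770_c0 (5.99-fold, 4.61 to 7.82) and comp19677_c0 (2.83-fold, 2.44 to 3.3), both with transcription factor terms.

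Among 14 membrane lipid genes, 4 were at least 2-fold higher and 1 lower, and the median of 0.07 lay at the 82.4th percentile. The highest were both genes of sulfolipid synthesis. Sulfoquinovosyltransferase (comp16284_c0) had 158 RPKM in LP against 8.94 RPKM in CK (17.7-fold, 15.8 to 19.8), and UDP-sulfoquinovose synthase (comp10353_c0) had 186 RPKM against 15.9 RPKM (11.7-fold, 10.8 to 12.7). A phospholipase D gene, comp26172_c0, was 2.64-fold lower (2.31 to 3.03). By product name, 1 of 8 phospholipase D genes was at least 2-fold higher and 1 lower, and of 8 phospholipase C genes 3 were higher and 0 lower. The 30 organic acid genes had a median of -0.03 (46.8th percentile) with 2 at least 2-fold higher, among them phosphoenolpyruvate carboxylase comp14466_c0 at 45 RPKM against 6.93 RPKM (6.5-fold, 5.95 to 7.11). The 10 genes of phosphate-sparing glycolysis had a median of -0.13 (22.8th percentile). Their highest members were NADP-dependent glyceraldehyde-3-phosphate dehydrogenase comp5803_c0, 3.82-fold higher (3.67 to 3.96), and comp23031_c0, a UTP-glucose-1-phosphate uridylyltransferase, 2.92-fold higher (2.84 to 3.01).

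**Figure D2:**
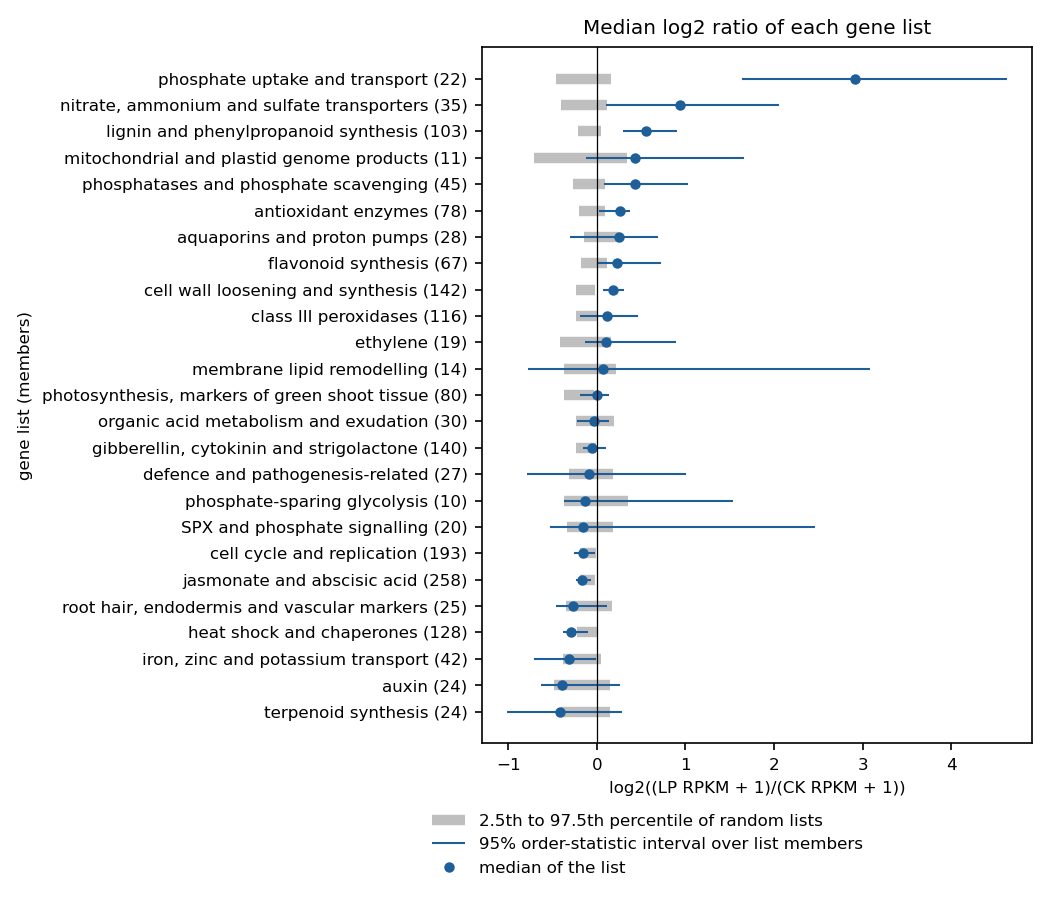
Median log2((LP + 1)/(CK + 1)) of RPKM (x axis) of each of the 25 gene lists (y axis, members in brackets). Points are medians, blue lines the 95% order-statistic interval over members, and grey bars the 2.5th to 97.5th percentile of 10000 random lists. The phosphate uptake list, at 2.91, lies furthest from its grey bar.

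Of the fixed lists of secondary metabolism, lignin and flavonoids leaned to LP and terpenoids to CK. Of 103 lignin and phenylpropanoid genes, 39 were at least 2-fold higher and 8 lower (median 0.56, 0.30 to 0.91, above all random lists). That median was 0.33 with at least 10 reads in each library and 0.20 by product names alone. Their highest member, comp17751_c0, is annotated as L-ascorbate oxidase with laccase terms and was 20.2-fold higher (15.8 to 26.1). The ferulate-5-hydroxylase gene comp24517_c0 was 7.63-fold lower (6.12 to 9.57). The KEGG phenylpropanoid pathway (215 genes) had 44 higher and 32 lower. Its median of -0.02 lay inside the middle range, at the 87.3rd percentile (96.8th after allowance for gene length). By product name, 0 of 7 phenylalanine ammonia-lyases were higher and 2 lower, against 5 and 0 of 14 cinnamoyl-CoA reductases. Of 67 flavonoid genes, 21 were at least 2-fold higher and 8 lower (median 0.23, 0.01 to 0.72, with 2 of 10000 random lists as high). Leucoanthocyanidin dioxygenase comp19195_c0 had 136 RPKM in LP and 14.7 RPKM in CK (9.29-fold, 8.3 to 10.4), whereas flavonol synthase comp31858_c0 was 21.8-fold lower (15.8 to 31.6). Of 24 terpenoid genes, 1 was at least 2-fold higher and 7 lower (median -0.41, -1.01 to 0.28, 2.1st percentile). A search of product names alone gave a terpenoid median of 0.01.

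Redox and cell wall genes had members on both sides, with list medians from 0.12 to 0.26. Of 116 genes matched as class III peroxidases, 27 were at least 2-fold higher and 16 lower (median 0.12, above all random lists). The ratio of their summed values was 0.94, and with at least 10 reads in each library the median was -0.08. Without the 11 members that other lists outside the middle range also hold, 10 of them in the antioxidant list, the median was -0.06 at the 79.1st percentile. The list also holds genes with other product names. Its highest named member is glycerophosphoinositol inositolphosphodiesterase comp9387_c0 and its lowest is peroxiredoxin 6 comp6035_c0. By product name, 82 peroxidases had 20 higher and 13 lower, with a median of -0.04 at the 88.0th percentile (97.4th after allowance for gene length). Peroxidase comp20256_c0 was 12.9-fold lower (11.6 to 14.4). Of 78 antioxidant genes, 16 were higher and 4 lower by the 2-fold limit (median 0.26, above all random lists), and 10 of them had 0 reads in CK. Their median was 0.08 with at least 10 reads in each library and 0.12 relative to genes of the same length and abundance, and the ratio of their summed values was 1.07. Without the 10 genes shared with the peroxidase list their median was 0.11 (98.4th percentile, 91.5th after allowance for gene length). Of 142 cell wall genes, 28 were higher and 13 lower (median 0.18, 0.07 to 0.31, above all random lists). The endoglucanase comp5610_c0 had 161 RPKM in LP and 8.84 RPKM in CK (18.2-fold, 16.2 to 20.6). Of 18 polygalacturonases, which cut pectin, 9 were at least 2-fold higher and 1 lower.

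Nitrogen genes went both ways. The list of 35 nitrate, ammonium and sulfate genes had 17 at least 2-fold higher and 5 lower (median 0.94, above all random lists), but a ratio of summed values of 0.97 and a median of 0.52 with at least 10 reads in each library and 0.57 at a mean of at least 5 RPKM. It contains 20 genes annotated as NO-forming nitrite reductase, all of which also carry laccase or lignin terms. Of the 15 others, 8 were higher and 3 lower, and 7 had 0 reads in CK. The ammonium transporter comp16516_c0 had 72.3 RPKM in LP and 0.14 RPKM in CK (537-fold, 233 to 2194, on 4 CK reads). Nitrate reductase comp16880_c0 had 17.9 RPKM against 123 RPKM (6.88-fold lower, 6.57 to 7.2). The nitrate transporter comp26314_c0, which the list does not hold, had 1.85 RPKM against 81.4 RPKM (44-fold lower, 37.9 to 51.3). By product name, 3 genes are nitrate/nitrite transporters of its NNP family, with 0 at least 2-fold higher and 2 lower. Those 3 genes summed to 14.66 RPKM in LP and 113.7 RPKM in CK. Of the 3 nitrate reductase genes, 2 were at least 2-fold higher and 1 lower, and 2 had 0 reads in CK. Their summed level was 29.53 RPKM in LP and 123.2 RPKM in CK. The 42 genes of iron, zinc and potassium transport had a median of -0.31 (8.5th percentile), 2 higher and 10 lower. Of these, ferritin comp23566_c0 was 4.28-fold higher (4.04 to 4.53) and nicotianamine synthase comp21745_c0, which makes a metal chelator, 9.9-fold lower (9.26 to 10.6). Another nicotianamine synthase gene, comp9316_c0, was 2.51-fold higher (2.1 to 3.02). Aquaporins and proton pumps (28 genes, 7 higher, 3 lower) had a median of 0.25 (97.3rd percentile), and of 0.04 relative to genes of the same length and abundance (61.6th). By product name, 5 of 6 NIP aquaporins were at least 2-fold higher and 3 of 10 PIP aquaporins at least 2-fold lower.

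None of the 4 hormone lists lay outside the middle range of random lists drawn from annotated genes, but 2 did under other settings. The auxin list (24 genes) had a median of -0.39 at the 7th percentile, the ethylene list (19 genes) 0.10 at the 93.7th, the jasmonate and abscisic acid list (258 genes) -0.17 at the 6.1st, and the gibberellin, cytokinin and strigolactone list (140 genes) -0.05 at the 87.8th. The last lay at the 98.5th after allowance for gene length (98.9th in 5 length bins), and the jasmonate and abscisic acid list at the 1.6th with all kept genes as the pool. Product names alone matched 31 jasmonate and abscisic acid genes, with a median of -0.60. They matched 21 gibberellin, cytokinin and strigolactone genes (median 0.27), 2 ethylene genes (0.05) and 0 auxin genes. The highest named member of the jasmonate and abscisic acid list is the PHS transporter comp25863_c0. Single genes of ethylene synthesis stood at both ends. The ACC oxidases comp25697_c0 and comp21662_c0 were 31-fold (26.6 to 36.1) and 26.4-fold (22.9 to 30.5) lower in LP, and comp14611_c0 was 44.2-fold higher (32.1 to 62.5). A gene with the same product name but a gibberellin 2-beta-dioxygenase term, comp16482_c0, had 283 RPKM in LP and 0.04 RPKM in CK, on 1 read (6813-fold, 1223 to 269103). Of 18 lipoxygenases, enzymes that start jasmonate synthesis, 3 were at least 2-fold higher and 7 lower. This group, chosen after the data were seen, had a median of -0.84 (-2.01 to -0.23) at the 0.1st percentile.

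Of 128 heat shock and chaperone genes, 110 stayed within 2-fold, 5 were higher and 13 lower (median -0.29, -0.38 to -0.10, 0.1st percentile). Their median was -0.13 relative to that of all genes and -0.11 relative to genes of the same length and abundance (0.9th percentile). Cell cycle and replication genes (193, with 10 higher and 19 lower) had a median of -0.16 at the 9.8th percentile, and at the 0.2nd after allowance for gene length. The 27 defence genes had a median of -0.09 (37.1st percentile). Chitinases among them lay on both sides, with comp26126_c0 at 340 RPKM against 2.37 RPKM (143-fold higher, 108 to 196) and comp26078_c0 at 133 RPKM against 512 RPKM (3.86-fold lower, 3.74 to 3.98).

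Markers of other tissue were measured in the same way. The 80 photosynthesis genes, markers of green shoot tissue, had a median of 0.0026 (99.1st percentile) with 5 higher and 13 lower, but their summed level was lower in LP, 736.2 RPKM against 1153 RPKM. The lowest named members were the photosystem genes PsbA (comp24767_c0) and PsbD (comp11200_c0), both plastid genes. PsbA had 49.1 RPKM in LP and 434 RPKM in CK (8.83-fold lower, 8.35 to 9.34), and PsbD 1.83 RPKM and 20.1 RPKM (11-fold lower, 8.06 to 15.3). Most of the difference in the summed level of the list lies in PsbA alone. Genes for the small chain of Rubisco, the carbon-fixing enzyme of green tissue, stood at the other end, with comp20871_c0 23.8-fold higher (14.4 to 42.8) and comp5107_c0 45.1-fold higher (15.3 to 220, on 3 CK reads). Root hair, endodermis and vascular markers (25 genes) had a median of -0.27 (7.2nd percentile). The list meant for mitochondrial and plastid genome products (11 genes) had a median of 0.43 (98.7th percentile), but it holds no plastid gene, and 3 of its members are cytochrome b-561, a nuclear-encoded membrane protein, and 2 are a cytochrome b subunit of succinate dehydrogenase. Its 6 cytochrome c oxidase subunit genes had a median of 0.42 (-2.31 to 0.64), with 0 higher and 1 lower. In all, 10 of the 25 lists lay above the 97.5th percentile and 2 below the 2.5th. Lists of genes drawn at random would give 1.2 outside. Genes of 1 family or pathway can vary together, so 1.2 is not the number to expect for such lists. Of 205 KEGG pathways, 35 lay above and 34 below. The 25 lists also share genes, 20 between the lignin and nitrate lists and 10 between the peroxidase and antioxidant lists, so the 10 lists above are not independent. Without the shared genes the peroxidase list falls inside. After allowance for gene length, 8 of the 10 and both of the lower lists stayed outside; photosynthesis (88th) and mitochondrial and plastid products (96.9th) did not, while gibberellin, cytokinin and strigolactone genes (98.5th) moved above. In 5 length bins, tried first, 7 of the 10 stayed outside, since class III peroxidases (91.7th) also moved inside, as did photosynthesis (93.3rd) and mitochondrial and plastid products (97.2nd).

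**Figure D3:**
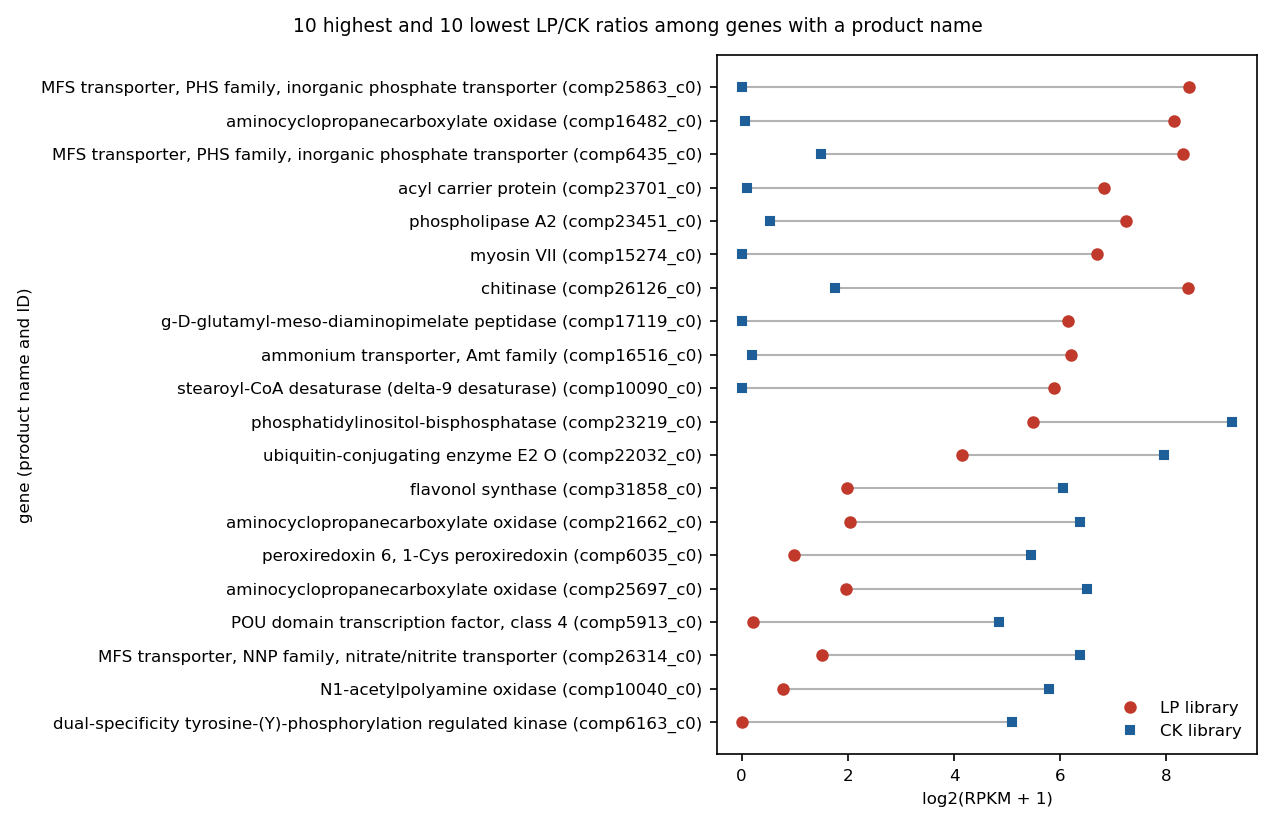
Level in the LP library (red circles) and CK library (blue squares), as log2(RPKM + 1) on the x axis, of the genes with the 10 highest and 10 lowest log2 ratios among genes with a product name. The top gene, comp25863_c0, has 342 RPKM in LP and 0 reads in CK.

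Outside the lists, the genes furthest apart included phospholipase A2 comp23451_c0 at 149 RPKM in LP against 0.44 RPKM in CK (341-fold, 146 to 1052), and an acyl carrier protein gene, comp23701_c0, at 112 RPKM against 0.08 RPKM on 1 CK read (1415-fold, 254 to 55902). A stearoyl-CoA desaturase gene, comp10090_c0, had 57.8 RPKM in LP and 0 reads in CK, at least 248-fold higher. Genes annotated as myosin VII (comp15274_c0, 103 RPKM in LP) and g-D-glutamyl-meso-diaminopimelate peptidase (comp17119_c0, 69.8 RPKM in LP) also had 0 reads in CK. Their product names were not checked against sequence, and whether they come from the tree or from another organism was not tested. At the other end, N1-acetylpolyamine oxidase comp10040_c0 was 76.2-fold lower (50.3 to 121), and the ubiquitin-conjugating enzyme E2 O gene comp22032_c0 had 16.8 RPKM in LP against 246 RPKM in CK (14.7-fold lower, 14.1 to 15.2). This enzyme family includes PHO2, which restrains phosphate uptake in Arabidopsis. A gene annotated as phosphatidylinositol-bisphosphatase, comp23219_c0, had 43.7 RPKM against 605 RPKM (13.9-fold lower, 13.3 to 14.4). Of the 10 most abundant genes, 8 were shared by the libraries, among them ubiquitin C comp25233_c0 with 13109 RPKM in LP and 10883 RPKM in CK and catalase comp18506_c0 with 3266 RPKM and 3431 RPKM.

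Across all 30843 genes kept, 2676 were at least 2-fold higher and 4996 at least 2-fold lower in LP, so 34.9% of these were higher. Higher genes were the larger side with a pseudocount of 5 (60.3%) and at 4-fold (59.7%). Relative to genes of the same length and abundance 54.2% were higher, but that setting centres each bin on its median and so evens the sides by construction. The median log2 ratio of all genes was -0.16, and ratios relative to it are larger by that amount. The excess of lower genes came from low levels: under a mean of 5 RPKM 1204 genes were higher and 3654 lower, while at 5 RPKM and above 1472 were higher and 1342 lower (52.3%). Gene length moved with the ratio. In 13192 genes with at least 100 reads in each library and a mean of at least 5 RPKM, Spearman's rho across genes was -0.35, and the median log2 ratio was -0.05 under 500 bases (560 genes), 0.16 at 500 to 1000 bases and -0.72 at 4000 bases and above. Genes are not independent replicates. Log2 RPKM of the libraries correlated across genes with Pearson's r = 0.82 and Spearman's rho = 0.776.

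Of genes at 5 RPKM or more in LP, 614 had 0 reads in CK, and 168 of these had a product name. In the other direction, 25 genes with at least 5 RPKM in CK had 0 reads in LP. At equal levels the smallest of the 614 would have had 12.9 reads in CK. The authors' deposited table calls 3416 genes, 1724 higher and 1692 lower in LP. In the authors' deposited table every call has an absolute log2 fold of at least 1 and a p-value of at most 0.05, with FDR up to 0.35, and 1668 of the calls have FDR under 0.05. Of the phosphate uptake list, the authors' deposited table calls 18 members higher and 0 lower.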

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

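The tests below were chosen after the result was seen, except the no-difference draws and the comparison of libraries within a group, which were set before.

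Of 313 genes in the ribosome pathway of the annotation, 91 had reads in LP and 0 reads in CK (29.1%, against 6.13% of the 4892 other genes with a pathway), while 4 had reads in CK alone. This drew attention because the fixed list of ribosomal proteins matched no gene, so no list of them was compared; the genes do enter the counts over all genes and the pathway scan, where 61 of 273 kept members were at least 2-fold higher and 6 lower, with a median of 0.17 and of -0.02 relative to genes of the same length and abundance. Depth argues poorly as the source: from their LP reads, 8.46 of the 313 genes would be expected at 0 in CK. RNA of a second organism in the LP library stays open, since a search for 15 products that fungi make and land plants are not known to make was void, with genes for 4 of them in the table (9 genes, 1 with LP reads and 0 CK reads). Copies of the tree's own genes that were expressed in LP alone stay open as well, as does a split of reads between near-identical copies, and the 91 genes together took 0.0116% of LP reads. They carry 73 product names, and 71 of these also had a gene with at least 10 reads in each library. The median LP level was 2.53 RPKM for the 91 genes and 82.9 RPKM for ribosome genes with at least 10 reads in each library. These values do not tell the open sources apart.

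The higher level of PHS family phosphate transporters in LP was weighed against the same source. For the 11 members with at least 10 CK reads the median log2 ratio was 2.83 (1.13 to 5.61). These members were chosen for their CK reads, so the choice itself leaves out an organism present in LP alone. The ratio cannot decide on an organism present in both libraries at unequal levels, which was not tested. The 8 members with fewer CK reads had LP levels from 4.17 RPKM to 342 RPKM. Of these, 5 lay above 12.9 RPKM, the highest level of the ribosomal genes at 0 in CK. A level does not show which organism a transcript came from, so that count cannot decide. For these 8 a second organism cannot be told apart from the tree's own response. Gene length and abundance argue little, as the median relative to genes of the same length and abundance was 3.47 (2.44 to 4.76). The phosphorus supply and an unrelated difference between the sampled plants cannot be told apart with 1 library in each group.

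Below a mean of 5 RPKM, genes lower in LP outnumbered genes higher in LP by 3.03 times. Counting noise of the shallower CK library argues poorly as the whole cause, since 20 draws of both libraries from a single level gave a mean of 22.5 lower genes there, against 3654 seen (21.1 with the level taken from pooled reads, the version run first). Gene length does not account for it either, as the ratio was 2.89 among the shortest of these genes (up to 248 bases, the lowest 25%) and 2.92 among the longest 25%. Poisson draws leave out errors in assigning reads to short assembled sequences and the steps before sequencing, which stay open, and no biological explanation was tested.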

How the results depend on the processing

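Each group has 1 library, so leaving out a replicate was not possible. No paired analysis was possible because each group has a single library. Settings named as added were chosen after the data were seen.

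The count of genes at least 2-fold higher (2676) and lower (4996) in LP was within 1.5 times of these values with a pseudocount of 0.1, no filter, median centring (3220 and 3980) and equal upper quartiles. It was 1530 and 1008 with a pseudocount of 5, 1472 and 1342 at a mean of at least 5 RPKM, and 1255 and 848 at 4-fold. Added settings gave 1157 and 2811 for genes with at least 10 reads in each library, 731 and 795 for genes with a product name, and 3282 and 2768 relative to genes of the same length and abundance. The filters and the 4-fold limit take fewer genes by construction. A larger pseudocount does so too, since it shrinks every ratio, and most of all those of low genes. Under a mean of 5 RPKM lay 3654 of the 4996 lower genes and 1204 of the 2676 higher genes. The side with more genes thus turned with the pseudocount of 5, the 5 RPKM filter and the 4-fold limit. The allowance for length and abundance centres each bin on its median, which evens the sides by construction, so it does not show which is larger.

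The phosphate uptake median of 2.91 stayed within its interval in all 7 alternatives. Product names alone match the same 22 genes, so that alternative could not differ, and median centring shifts all genes alike. The phosphatase list (0.43) came to 1.34 from summed values and 1.33 from product names alone, where the cause was not tested. Of the 12 lists outside the middle range of random lists, 8 kept their sign in every setting run, and it reversed for class III peroxidases from summed values (-0.09) and at 10 reads in each library (-0.08, added) and without genes shared with other such lists (-0.06, added), nitrate and ammonium from summed values (-0.05), photosynthesis from summed values (-0.65), and terpenoids from product names alone (0.01). Summed values weigh abundant members more. All 13 lists inside the middle range took the other sign in at least 1 setting, for example phosphate signalling (2.17), aquaporins (-0.28), ethylene (-0.23), auxin (0.03), gibberellin (0.38), cell cycle (0.19) and defence (0.11) from summed values and iron, zinc and potassium (0.24) from product names. Of 348 values of named genes under other settings, 216 shifted by less than the counting interval, 129 kept their sign but shifted by more or, for 57 values of 19 genes with 0 reads in a library, had no interval, and 3 reversed, all by centring: comp17575_c0 (0.04), comp19451_c0 (0.05) and comp18506_c0 (0.09).

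Genes at 0 in CK numbered 329 and genes at 0 in LP 7 with at least 10 RPKM in the other library (added), a stricter limit by construction. In the authors' deposited table, FDR under 0.01 with 2-fold leaves 684 higher and 451 lower, and FDR under 0.05 (added) leaves 996 and 672, fewer by construction. Lists above and below the middle range (10 and 2) numbered 9 and 3 with all kept genes as the pool, the version run first, and 9 and 3 after allowance for length in 10 bins and 8 and 3 in 5 bins (both added). Depth limits CK most: 3 reads on 1000 bases stand for 0.168 RPKM there and 0.0619 RPKM in LP.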

Other observations

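A scan of 205 KEGG pathways with at least 15 members, chosen after the data were seen, set each median against 1000 random lists of genes with a pathway. Above the 97.5th percentile lay 35 pathways and below the 2.5th lay 34, and 23 and 17 of these held after allowance for gene length. Fatty acid biosynthesis (37 genes) had 8 members at least 2-fold higher in LP and 0 lower, with a median log2 ratio of 0.37, and ether lipid metabolism (27 genes) had 7 and 1, with a median of 0.31. Glycerolipid metabolism (63 genes, 8 and 2), glycerophospholipid metabolism (71 genes, 11 and 2) and arachidonic acid metabolism (32 genes, 7 and 0) also lay above the 97.5th percentile, before and after allowance for length, while others lay inside, among them fatty acid metabolism (2 and 2, 41.4th percentile), sphingolipid metabolism (4 and 4, 50.5th) and alpha-linolenic acid metabolism (9 and 12, 11.9th). Diterpenoid biosynthesis (20 genes) had a median of 0.63, with 7 higher and 4 lower, unlike the fixed terpenoid list. Sulfur metabolism (28 genes) had 10 higher and 0 lower, at the 95.5th percentile (97.6th after allowance for length), and 6 of the 28 had 0 CK reads.

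DNA replication (82 genes) had 0 members at least 2-fold higher and 14 lower, with a median of -0.45 and of -0.21 relative to genes of the same length and abundance. Mismatch repair (62 genes) had 0 and 14, with medians of -0.58 and -0.17, and nucleotide excision repair (90 genes) 1 and 22, with -0.37 and -0.17. These pathways share members. Other repair pathways were base excision repair (71 genes, 1 and 12), with medians of -0.31 and -0.18, and 2 more. Homologous recombination (59 genes, 0 and 6) lay at the 1.1st percentile, but at the 10.3rd after allowance for gene length. Non-homologous end-joining (16 genes, 0 and 1) lay inside the middle range, at the 13.6th and 20.5th. The plant circadian rhythm pathway (62 genes) had 3 higher and 17 lower, with medians of -0.40 and -0.34, and of the 10 genes annotated as phytochrome B, a red light receptor, 0 were higher and 5 lower. Of 14 AP2-like factors of the ANT lineage, 7 were at least 2-fold higher and 0 lower, and 4 of the 14 had 0 CK reads, while of 61 EREBP-like factors 5 were higher and 19 lower.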
